A study of Mus musculus with 6 samples.

How the data were processed

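RNA from 2 sorted fractions of mouse mammary cells was measured on 6 Agilent 2-colour arrays, 3 per fraction. The cells came from mammary glands of virgin C57/B6 mice that carry EGFP in the Lgr5 locus, per the labels, and lay in the Lin-negative, CD24-positive, CD29-high gate called P4. EGFP then split that gate into Lgr5-positive and Lgr5-negative cells. The labels do not list the markers behind Lin. Each sample was labelled with Cy5, and a universal mouse reference RNA, a mix of 11 cell lines, with Cy3. This held on each of the 6 arrays, so no dyes were swapped. A dye effect that is constant for a probe is thus shared by both groups. One that varies with brightness need not be, since Cy5 signal was lower on the Lgr5-positive arrays.

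The authors deposited 1 scanner file per array, made with Agilent Feature Extraction 11.0 per the submitters' processing notes and version 11.0.1.1 per the file headers. These files hold the intensity of each spot and of its local background in both channels as medians of pixel brightness, the software's processed intensity after background subtraction and dye normalization, and a log10 ratio of processed Cy5 over Cy3, per the file headers. A value table deposited for the whole series holds log2 ratios. The values themselves show that 100% of its probes have a median of 0 over the 6 arrays and that 81.6% to 83.2% of its values lie within 0.001 of the scanner's log2 ratio centred in that way. The correlation with that centred ratio was 0.920 to 0.950 across probes, with the same direction on each array, and the column medians were -0.0016, 0.03 and 0.02 for Lgr5-positive replicates 1 to 3 and 0.0064, -0.02 and -0.05 for Lgr5-negative replicates 1 to 3. What made the remaining values differ is not known.

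Median spot signals were corrected with normexp (offset 50) against the median background and normalized by loess within each array in limma 3.58.1 under R 4.3.3. The design set before the data were examined had named mean spot signals, which the files used here do not hold, so the medians took their place, also in the alternative without background subtraction. Control spots and spots with an outlier flag had weight 0 in the loess and were then left out. Spots of one probe were averaged, giving 55681 probes. Probes were named through their RefSeq transcripts with a table of assembly GRCm38.p6, used for names alone because the arrays are annotated on mm9. Of 26585 mRNA accessions on the array, 26166 matched, and 27509 probes received 1 of 20887 gene symbols. A probe was kept when its Cy5 signal was well above background on at least 3 of the 6 arrays, which left 34552 probes. The probe with the highest mean brightness stood for a gene, and 15680 genes were tested after 10 with a spot flagged as an outlier were left out. Where only 1 of the probes of a named gene passed, or they differed in sign or widely in size, the other value is stated.

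Lgr5-positive and Lgr5-negative arrays were compared with limma's lmFit and eBayes on log2 (Cy5/Cy3), with the group as the only term, two-sided, at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are positive minus negative. The named genes follow a rule set before the data were examined. It takes Lgr5, then per direction up to 12 genes past the threshold with the largest change, with no overlap between the groups and Cy5 signal well above background on all 3 arrays of the higher group, filled up to 6 by the lowest p where fewer passed. In each list it takes the members past the threshold, up to 4, or else the 2 with the lowest p. For 24 gene lists fixed at the same time, which name 371 genes of which 334 were tested, limma's camera was run with a preset inter-gene correlation of 0.01, and with an estimated correlation and fry as alternatives. A gene whose Cy5 signal was not well above background on any array of a group has only a bound there. Its fold is given as "at least", from the Cy5 channel after loess and Aquantile normalization, which is open to dye bias, and left out where it exceeds the fold of the log2 ratio. Such a bound holds for that normalization only.

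The replicate numbers 1 to 3 occur in both groups. Arrays with the same number deviated together from their group means, with correlations across genes of 0.810, 0.819 and 0.675 for numbers 1, 2 and 3. Those of arrays with different numbers lay between -0.67 and -0.16. Deviations within a group of 3 sum to 0, which pushes these below 0, so their sign is no separate evidence of pairing. By the criterion used, a correlation over 0.1 in each pair, the numbers pair the arrays; this was decided before the calls of the 2 fits were compared. Same-numbered arrays were also neighbours on the slide, with the Lgr5-positive array in the column before the Lgr5-negative one, so slide position and group cannot be told apart within a pair. The fit with the replicate number as a block was planned as an alternative. Its calls are stated beside the others where it changed the call of a named gene or list or moved a count by over 1.5 times. All 6 arrays lay on 1 slide and were read in 1 scan. The labels do not say that the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

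The precision is limited by the number of arrays. Simulated data for the 15680 genes, with 50 genes changed at each of 4 sizes, were used to test both fits. They kept the observed differences between replicate numbers, with noise of the blocked fit's variances that was independent between genes. The group-only fit counts the differences between replicate numbers as noise, so this setting makes its false calls rare. With the group alone, 0% of genes changed 1.5-fold were called, 2% at 2-fold, 72% at 4-fold and 96% at 8-fold, with 0 false calls. With the block, 56%, 100%, 100% and 100% were called, with 28 false calls. Over 10 such simulations the block gave 203 false calls among 1959, or 10.4%, above the 5% that the threshold aims at, and the group-only fit 0 of 783; the block with a trended and robust variance gave 10.5%. A simulated shift of the interferon list was recovered, and 0 of the other 23 lists were called. The simulated noise was independent between genes, whereas the estimated correlation was 0.39 in the interferon list and 0.45 in the endothelial list. The simulation therefore does not test the list calls under such correlation.

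The alternatives covered background correction, the scanner's own ratios, median centring, Aquantile, the Cy5 channel alone, the deposited value table, 3 other filters on dim probes, the median over a gene's probes, array weights, a trended and robust variance, the replicate block, the list test, and leaving out each array and each pair. The alternatives within the block, the genes named from it, the count of false calls over 10 simulations, and 5 further marker lists were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.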

Results

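Lgr5-positive and Lgr5-negative cells were compared on 6 arrays. Both came from the CD24-positive, CD29-high mammary gate, which is enriched in basal cells and in cells that can regenerate a gland, and differed in EGFP from the Lgr5 locus. Lgr5 is a receptor for R-spondins that marks stem cells in several epithelia. There were 3 arrays per group. Median Cy5 signal was 137, 161 and 169 on the Lgr5-positive arrays of replicates 1 to 3, and 200, 208 and 278 on the Lgr5-negative ones, against a median Cy5 background of 64 to 76. The Lgr5-positive array was the dimmer one in all 3 pairs. Over groups the median signal was 156 ± 16.7 and 229 ± 42.9 (SD, n = 3 each). A two-sided exact permutation test that ignores the pairing gave p = 0.1, the smallest p that 3 against 3 allows. Between 50.9% and 74.4% of probes were well above background in Cy5, and 0 spots were saturated. Log2 ratios correlated at 0.844 to 0.922 across genes between arrays with the same replicate number, at 0.814 to 0.871 between arrays of one group, and at 0.726 to 0.819 between arrays that shared neither.

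Lgr5 itself, read by a single probe, had a log2 ratio to the reference of 4.87 ± 0.57 (SD, n = 3) in Lgr5-positive cells and 3.40 ± 0.61 (SD, n = 3) in Lgr5-negative cells. The difference was 1.47 (SE 0.40), or 2.77-fold, and lay in the direction of the labels in each pair (1.40, 1.31 and 1.70 for replicates 1 to 3). All 6 arrays were well above background, so Lgr5 transcript was also measured in the negative fraction. The adjusted p was 0.245 with the group alone and 0.0021 with the replicate block (SE 0.13).

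The main question was which genes separate Lgr5-positive cells from the other cells of the gate. The transcripts with the largest differences were lower in Lgr5-positive cells. Tspan8, a tetraspanin, led the genes that were higher, at 11.0-fold. In all, 96 of 15680 genes changed with the group alone, 4 higher and 92 lower, all by at least 2-fold. With the replicate block 1210 changed, 330 higher and 880 lower, of which 622 (54 higher, 568 lower) changed at least 2-fold, and these 1210 included all of the 96. In simulated data 10.4% of the blocked calls were false, above the 5% that the threshold aims at, against 0% with the group alone. These shares belong to the simulated setting and were not measured for the 96 or the 1210 calls. At an unadjusted p under 0.05 there were 1285 and 3347 genes, where chance alone gives about 5% of the genes tested. The groups did not overlap in 1912 genes (12.2%), where chance gives 10% if the arrays are unpaired. The difference had one direction in all 3 pairs in 6946 genes (44.3%; 3526 higher, 3420 lower), where chance gives 25% for independent pairs.

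The 4 genes that rose with the group alone were Tspan8, Slpi, Crhr1 and Adamts2. Tspan8 had a log2 fold change of 3.46 (SE 0.32, adjusted p = 0.015), from 0.81 ± 0.44 to 4.26 ± 0.47 (SD, n = 3). Slpi, a secreted inhibitor of serine proteases, rose by 1.95 (SE 0.25, adjusted p = 0.035). Crhr1, a receptor for corticotropin-releasing hormone, rose by 1.31 (SE 0.19, adjusted p = 0.048). Adamts2, which trims procollagen, rose by 1.15 (SE 0.17, adjusted p = 0.049), whereas a dimmer Adamts2 probe gave 0.0047. Gfra2, a co-receptor for neurturin, and Thbs3, a thrombospondin, did not pass, with log2 fold changes of 1.08 and 1.47 and an adjusted p of 0.056 for each; both passed with the block, at 0.0048. Each of these 6 genes was higher in all 3 pairs, which follows from the rule that named groups must not overlap.

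Naming by the same rule within the blocked fit, a choice made after the data had been seen, added 8 genes that rose there and not with the group alone. They were Nox4 (1.66, SE 0.12), an oxidase that makes hydrogen peroxide, Plppr3 (1.46, SE 0.14), Fgg (1.43, SE 0.16), the gamma chain of fibrinogen, and Krtap17-1 (1.43, SE 0.14). The others were Ptx3 (1.41, SE 0.15), a soluble pattern receptor, Ildr1 (1.37, SE 0.13), Nme5 (1.35, SE 0.13) and Ly6h (1.34, SE 0.13). Their adjusted p in the blocked limma fit lay between 0.0013 for Nox4 and 0.0046 for Fgg, against 0.084 to 0.259 with the group alone. Second probes gave 0.17 for Nox4, 0.52 for Nme5 and 0.55 for Ly6h.

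Among the named genes that fell, Fut7, a fucosyltransferase that builds selectin ligands, had the largest change in the main processing, -4.75 (SE 0.31, adjusted p = 0.0069), or 26.9-fold. Not all settings kept this order: with the scanner's ratios Bst1 was at -5.45 and Fut7 at -4.57. Cxcl13, a chemokine of lymphoid tissue that attracts B cells, fell by 4.17 (SE 0.34, adjusted p = 0.0097), but its value was -2.09 with the scanner's ratios and with the deposited table (adjusted p = 0.071 in each) and -5.51 in the Cy5 channel alone. Lyve1, a hyaluronan receptor of lymphatic endothelium, fell by 4.12 (SE 0.57, adjusted p = 0.044), and Gcnt1, a glycosyltransferase that branches O-glycans, by 4.30 (SE 0.53, adjusted p = 0.033). Bst1, an ADP-ribosyl cyclase of stromal and myeloid cells, fell by 4.51 (SE 0.45, adjusted p = 0.018), and Enpp2, the enzyme autotaxin, by 4.50 (SE 0.53, adjusted p = 0.029). Cxcl13, Gcnt1 and Bst1 were well above background on only 2 of the 3 Lgr5-positive arrays. Wdr64 fell by 4.60, Serpina3f by 4.33, Cd55, a brake on complement, by 4.04, and Tgfbi, an extracellular matrix protein, by 4.00, with adjusted p between 0.0085 and 0.049. Serpina1a fell by 4.02 (adjusted p = 0.0085), but like Serpina3f it belongs to a family with near-identical copies, so the copy is uncertain. The carboxylesterase Ces2g was not well above background on any Lgr5-positive array and was at least 16.7-fold lower by the bound used here (adjusted p = 0.011). In the quantile-normalized Cy5 channel alone its log2 fold change was -3.89, a smaller fall, so this bound is not a strict limit. All 12 were lower in 3 of 3 pairs, which the naming rule's demand for no overlap between the groups ensures. Second probes gave -2.79 for Fut7, -2.06 for Bst1, -3.14 for Serpina3f and -2.87 for Serpina1a.

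**Figure D1:**
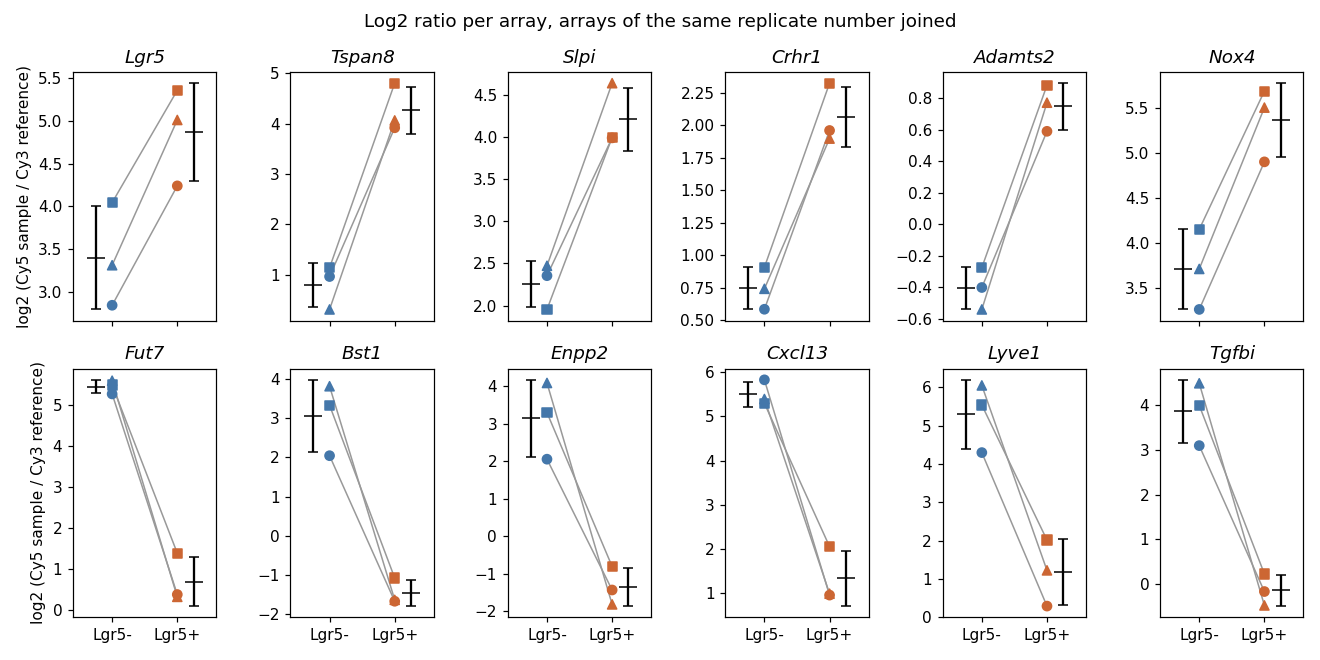
Log2 ratio of Cy5 sample over Cy3 reference on the vertical axis for 12 named genes, in Lgr5-negative (blue) and Lgr5-positive (orange) cells, 1 point per array, with arrays of one replicate number joined (circle 1, square 2, triangle 3). Black bars are the mean and SD of each group (n = 3). Lgr5 keeps nearly the same step of 1.40, 1.31 and 1.70 in the pairs while the pairs lie at different levels, and Fut7 differs by -4.75 on average.

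Some of these calls were close to the threshold. Over the alternative settings that keep all arrays the call was lost in 9 of 14 for Adamts2, Cd55 and Klf2, 7 of 14 for Crhr1, 6 of 14 for Lyve1, 4 of 14 for Slpi and Plvap, 7 of 12 for Tie1 and 2 of 13 for Cxcl13. It was lost in at most 1 of these for the other genes named as passing with the group alone. The settings include Aquantile, which leaves ratios as they are. They also count the scanner's ratios and the deposited table separately, though these largely hold the same ratios. Blocked calls were lost in 8 of 13 such settings for Id1, 5 of 13 for Oxtr, 4 of 13 for Lcn2, 3 of 13 for Jun and 1 of 13 for Rab25. They were lost in 2 of 11 to 13 settings for Cd14, Cd74, Pi16, Notch3, Ndufa4l2, Ngfr, Nfkbia, Tie1 and Egln3. Under median centring Oxtr was at 0.29 and Lcn2 at 0.21, with an adjusted p of 0.115 and 0.217. With the scanner's ratios and with the deposited table the value was 2.81 for Ildr1, -2.22 for Des, -2.76 for Foxc2 and -1.31 for H2-Aa. It was -6.24 for Ces2g, -5.45 for Bst1 and -4.94 for Gcnt1 there, and -2.16 and -1.76 for Tie1. Ces2g and Tie1 were not well above background on any Lgr5-positive array, so their values are not exact sizes. List members named only for their blocked call, such as Krt17, Cdh3, Sox10, Myl9, Smtn and Cnn1, were not followed through these settings. Without some arrays or pairs no gene passed with the group alone. The count depended on single arrays and on scaling. It was 0 without Lgr5-positive replicate 1 or 3, 0 without pair 2 or pair 3, 5 and 21 without Lgr5-negative replicate 2 or 3, and 371 without Lgr5-negative replicate 1, and in the blocked fit it was 326 (37 higher, 289 lower) without pair 2. Median centring in place of loess shifted the median of all genes to -0.29 and gave 9 genes, all lower, and 5790 in the blocked fit, of which 128 were higher and 5662 lower (97.8% lower against 72.7%).

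Genes of blood vessel endothelium fell as a group. The median of the 11 tested endothelial markers was -2.04 (4.12-fold lower), 3 fell over all genes tested and 9 when adjusted over the list alone, and 8 fell with the block. Egfl7, a protein that endothelial cells secrete, fell by 3.30 (SE 0.38, adjusted p = 0.029) and Plvap, a component of endothelial diaphragms, by 2.41 (SE 0.31, adjusted p = 0.035), with -1.02 on a second Plvap probe. Tie1, an endothelial receptor kinase, was not well above background on any Lgr5-positive array and fell (adjusted p = 0.048). Kdr, a receptor for VEGF, was at 0.18 on its brightest probe and -2.66 on another. Camera gave the list an adjusted p of 1.13e-12 with the preset correlation; with an estimated correlation the adjusted p was 0.227. Mural and connective tissue lists lay lower too. The pericyte list had a median of -0.42 (adjusted p = 0.0082, and adjusted p = 0.227 with an estimated correlation; 0 of 9 members past the test, 3 of 9 with the block, 0 over the list alone), with Notch3 at -0.89 and Ndufa4l2 at -0.86, which fell with the block. The fibroblast list had a median of -0.34 (adjusted p = 0.0035, and adjusted p = 0.227 with an estimated correlation; 0 of 11 members past the test, 4 lower over the list alone), with Dcn at -1.37 and Pi16 at -1.26. With the block 5 fibroblast markers fell, Dcn and Pi16 among them, and 1, Fbln1, rose (0.99, with 0.39 on a second probe that did not pass). Leukocyte markers had a median of -0.07 (16 members, adjusted p = 0.310), with Cd74 at -1.04, which fell with the block (adjusted p = 0.022), and H2-Aa at -0.56, which did not. In the blocked fit with the scanner's ratios H2-Aa passed (adjusted p = 0.031) and Cd74 did not (0.051), as with the deposited table (0.030 and 0.051), and H2-Aa also passed under median centring (0.029).

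Basal and contractile genes were shifted upward by small amounts. The basal and stem-associated list had a median of 0.39 over 24 genes, of which Tspan8 rose and 20 had positive values; over the list alone 1 rose and 1 fell. With the block Krt17, Cdh3, Sox10 and Tspan8 rose, and Procr, a receptor of activated protein C that endothelium also carries, fell (-2.43, SE 0.53; adjusted p = 0.139 with the group alone). Contractile genes had a median of 0.41 over 15 genes. None passed the limma test over all genes (0 of 15; 4 higher and 1 lower over the list alone), while with the block Oxtr, the oxytocin receptor, at 0.76, Myl9, Smtn (0.60, with 0.47 on a second probe that did not pass) and Cnn1 rose and Des, at -0.97, fell. Wnt pathway targets and feedback genes had a median of 0.30 over 15 genes, 0 of them past the test and 1 lower over the list alone; Wif1, a secreted Wnt inhibitor, was at 1.11 and rose with the block together with Sox9, and the cyclin gene Ccnd1 was at -2.01 and fell with it. Camera's adjusted p was 5.3e-04 for the basal list, 1.4e-04 for the contractile list and 0.013 for the Wnt list. With an estimated correlation the adjusted p was 0.227 for each, and the endothelial list moved the other way on the same arrays (median -2.04). Whether these shifts are linked was not tested. Without Tspan8 the basal list's median was 0.36. Under median centring the medians were -0.03, 0.10 and -0.13, which lay 0.26, 0.39 and 0.17 above the median of all genes, and array weights ended the call of the Wnt list (adjusted p = 0.070), as did leaving out Lgr5-positive replicate 3 (0.092), Lgr5-negative replicate 1 (0.110), pair 1 (0.058) or pair 3 (0.089).

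Genes of hormone-sensing luminal cells were lower. The list's median was -1.04 over 12 genes (camera adjusted p = 1.7e-05; 0.227 with an estimated correlation), with 0 past the limma test over all genes and 7 lower and 1 higher over the list alone. Ly6a (Sca-1) was at -1.63 and Foxa1, a partner of the estrogen receptor, at -0.98. With the block 8 fell and Tbx3 rose; those that fell included Ly6a, Foxa1, Areg (-2.25), a growth factor induced by estrogen, Esr1, the estrogen receptor itself (-1.26, with -0.14 on a second probe), and Wnt4 (-1.30), and Tnfsf11 was not well above background on any Lgr5-positive array (at least 3.51-fold lower). The fry test called this list in the blocked fit (adjusted p = 0.0065). Luminal progenitor and milk genes had a median of -0.19 (12 genes, adjusted p = 0.269), with Cd14 at -1.28 and Lcn2 at 0.62; with the block 2 fell, Cd14 among them (adjusted p = 0.030), and Lcn2 rose (adjusted p = 0.032). Without Ly6a the median of the hormone-sensing list was -0.98 (camera p = 4.6e-05 with the preset correlation, group alone). The endothelial median of -2.04 stood beside these shifts, and a link between them was not tested.

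Interferon-stimulated and NF-kappaB genes were lower together. Of 20 interferon-stimulated genes 19 had negative values, with a median of -0.86; 0 passed over all genes, 8 were lower over the list alone and 12 fell with the block. Bst2, which tethers virions, was at -1.09 (SE 0.17) and Lgals3bp at -1.18 (SE 0.19), with adjusted p of 0.056 and 0.061; both fell with the block, and a second Lgals3bp probe gave -0.33. All 16 NF-kappaB and chemokine genes had negative values (median -0.71), 0 passed, 2 were lower over the list alone and 7 fell with the block; Tnfaip3, a feedback inhibitor of NF-kappaB, was at -1.97 and Nfkbia at -1.17, and both fell with the block. Camera's adjusted p was 1.8e-12 and 1.1e-07, and with an estimated correlation the adjusted p was 0.227 for both. The median of the NF-kappaB list was -0.26, -0.60 and -1.32 in the 3 pairs. The endothelial list fell on the same arrays, and a link of the NF-kappaB list to it was not tested.

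Notch pathway genes had a median of -0.30 over 15 genes (camera adjusted p = 0.0035; 0.230 with an estimated correlation). Mfng, which modifies Notch receptors, fell by 2.72 (SE 0.30, adjusted p = 0.028; -1.82 on a second probe), and 2 were lower over the list alone. Notch4, a receptor found mainly in endothelium, was at -1.10, and with the block 4 members fell, Mfng and Notch4 among them. The call ended under median centring (0.088) and without Lgr5-positive replicate 1 (0.063). Epidermis and hair follicle markers had a median of -0.83 over 10 genes (adjusted p = 0.0027; 0.227 with an estimated correlation), 0 of them past the test and 1 lower over the list alone. Cd34, at -2.58 (-0.46 on a second probe), is also carried by endothelium, Krt6a was at -1.91, and these fell with the block together with Krt1. The median was -0.85, -1.54 and -0.05 in the 3 pairs and -1.52 to -0.11 over the settings that keep all arrays. The call ended among probes well above background on all 6 arrays (median -0.11, adjusted p = 0.132) and without Lgr5-negative replicate 1 (0.101). Without that array the fibroblast and pericyte calls ended too (0.067 for both), and the pericyte call also ended among probes well above background on all 6 arrays (0.103). The pericyte and epidermis calls ended without pair 1 as well (0.058 for both). The endothelial list's median of -2.04 stood beside both of these groups, and a link to it was not tested.

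**Figure D2:**
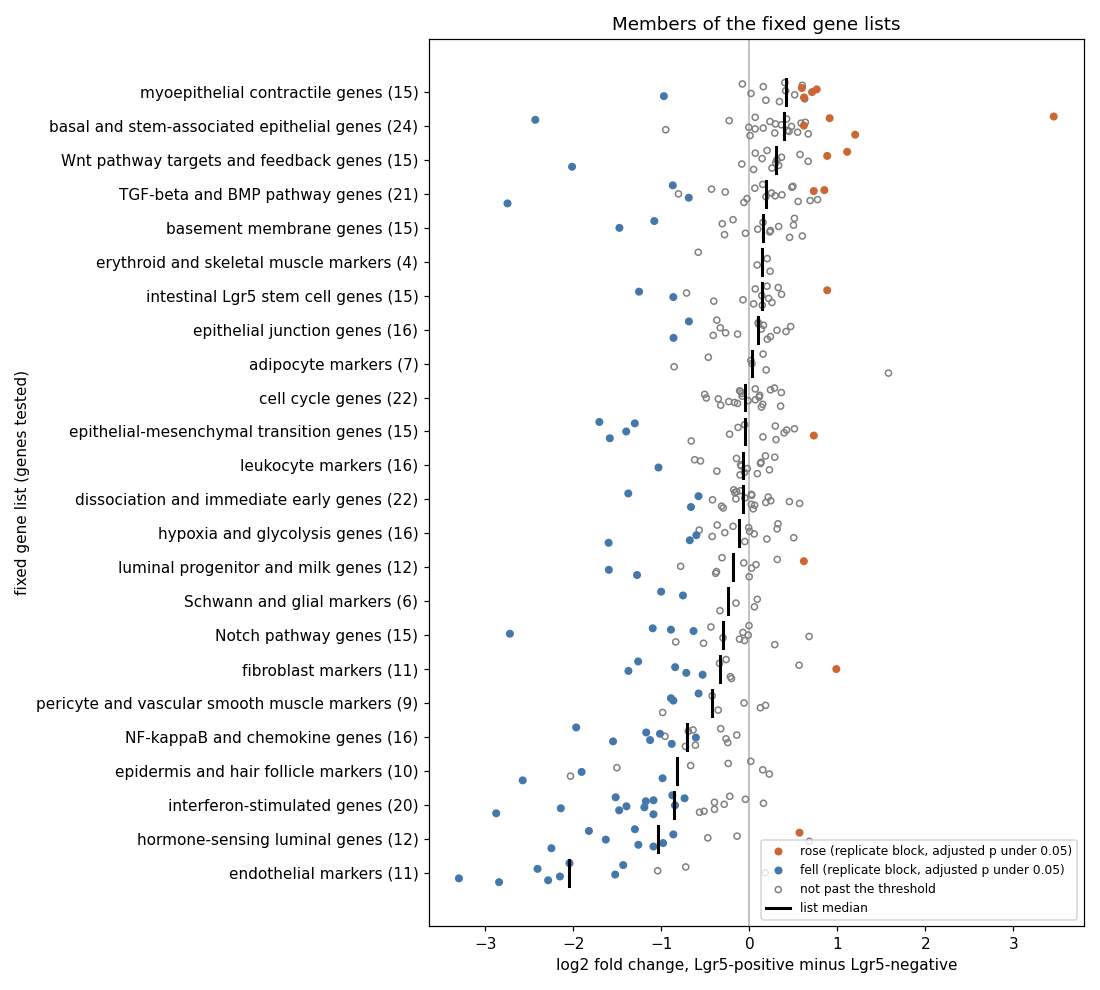
Log2 fold change of Lgr5-positive minus Lgr5-negative cells on the horizontal axis for each tested member of the 24 fixed lists, 1 point per gene (vertical position within a list has no meaning), with the number of genes tested beside each list. Black bars are list medians, filled points passed the fit with the replicate block, and open points did not; the medians run from -2.04 for endothelial markers to 0.41 for contractile genes.

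The remaining lists were not called. The Schwann list was called when dim probes were not filtered out (median -0.32, adjusted p = 0.031). Calls also appeared without single arrays, for the leukocyte list without Lgr5-positive replicate 1 or Lgr5-negative replicate 2 (0.026 in each), the hypoxia list without Lgr5-positive replicate 3 (0.029) and the basement membrane list without Lgr5-negative replicate 2 (0.021). Their medians were 0.03 for 7 adipocyte markers, -0.24 for 6 Schwann and glial markers, 0.15 for 4 erythroid and skeletal muscle markers, 0.14 for 15 intestinal Lgr5 stem cell genes and 0.19 for 21 TGF-beta and BMP genes. They were -0.05 for 15 epithelial-mesenchymal transition genes, 0.10 for 16 junction genes, -0.05 for 22 cell cycle genes, -0.08 for 22 dissociation and immediate early genes, 0.15 for 15 basement membrane genes and -0.12 for 16 hypoxia genes, with camera adjusted p from 0.203 to 0.928. The adipocyte, erythroid, intestinal, TGF-beta, junction and basement membrane lists had a median, mean and test that differed in sign. In the dissociation and immediate early list Klf2, a flow-induced transcription factor, fell (-1.38, adjusted p = 0.049). Adjusted over the list alone, 1 intestinal, 1 immediate early and 1 hypoxia gene were lower, and 1 transition gene was higher and 4 were lower. Values of the members with the lowest p were -0.86 for Fabp4, 1.58 for Cfd, -0.75 for Ngfr, -0.58 for Tnnt3 and 0.24 for Acta1. They were -1.25 for Smoc2, -0.86 for Prom1, -2.75 for Bmp2, -0.69 for Id1, -1.59 for Foxc2, -1.40 for Snai1, -0.86 for Cgn, -0.69 for Rab25, -0.51 for Mki67 and -0.49 for Mcm3. Jun was at -0.58, Col18a1 at 0.60, Lama4 at -1.48, Adm at -1.60 and Egln3 at -0.60. With the block Bmp2 (adjusted p = 6.3e-04), Foxc2 (0.0016), Smoc2 (0.0025), Snai1 (0.0052), Adm (0.0079), Lama4, Prom1, Cgn, Jun, Rab25, Egln3, Ngfr and Id1 (0.048) fell as well, while Fabp4, Cfd, Tnnt3, Acta1, Mki67, Mcm3 and Col18a1 did not pass. In other blocked settings Cfd passed in 6 of 13 (adjusted p of 0.014 to 0.048), Fabp4 in the Cy5 channel alone (-1.62, 0.0033), Mki67 with array weights (0.040), and Fabp4 (0.0037), Tnnt3 (0.034), Mki67 (0.0017) and Mcm3 (0.0028) under median centring. Second probes gave -0.41 for Egln3, which did not pass with the block, and -0.59 for Mki67, which did. Counts with the block were 2 higher and 3 lower for TGF-beta, 1 and 4 for transition, 1 and 2 for intestinal genes, 3 lower each for immediate early and hypoxia, 2 lower each for Schwann, junction and basement membrane, and 0 for adipocyte, erythroid and cell cycle genes. Under median centring the other lower lists lay below the median of all genes by these amounts: endothelial -1.76, hormone-sensing -0.93, interferon -0.88, NF-kappaB -0.74, epidermis -0.61, fibroblast -0.44, pericyte -0.28 and Notch -0.18. The cell cycle and immediate early lists were called there (medians -0.47 and -0.48, adjusted p = 0.018 and 0.037). Over all 24 lists camera called 11 (3 higher, 8 lower) in either fit, the same 11 lists in both. With an estimated correlation it called 0 lists, with an adjusted p of 0.227 to 0.230 for these 11 and 0.496 for each of them in the blocked fit. The fry test called 0 with the group alone and 5 with the block, all lower: the hormone-sensing, fibroblast, pericyte, Schwann and Notch lists.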

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

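One probe outside the gene-level comparisons, A_30_P01029340, was higher in Lgr5-positive cells; it carries no gene name and lies on chromosome 6, in the region from 129151512 to 129208737 (mm9, per the array file). Its log2 fold change was 1.70 (SE 0.17), 3.24-fold, with a limma adjusted p of 0.042 over 34528 probes. Of 14969 probes without a gene name, 3 changed with the group alone (1 higher, 2 lower) and 178 with the replicate block (76 higher, 102 lower). No explanation was tested.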

How the results depend on the processing

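The alternatives within the blocked fit were chosen after seeing the data; the others were planned. The count of 96 genes became 9 under median centring, 44 among genes well above background on all 6 arrays (fewer genes tested), 312 with array weights, 55 with a trended and robust variance, 35 for probes in place of genes (more tests) and 1210 with the replicate block; for the others the cause was not tested. It lay between 0 and 371 without a single array or a pair, and between 64 and 106 in the other settings. At 0 calls, 667 to 1103 genes had an unadjusted p under 0.05, where chance alone gives about 5% of the genes tested. The counts without pair 3 (667) and without pair 2 (770) lay below that share. Lgr5 stayed at 0.92 to 1.51 in the planned settings and crossed the threshold only with the replicate block, at 1.47 (adjusted p = 0.0021, against 0.150 to 0.355 in the others); without an array or a pair it was 1.19 to 1.79. The count of 11 lists became 0 with an estimated correlation, 0 by fry and 0 with the replicate block and an estimated correlation; it was 7 to 13 without an array or a pair, with 7 without Lgr5-negative replicate 1. The block's count of 1210 became 738 with the scanner's ratios, 5790 under median centring and 753 with the deposited value table, and 326 to 1398 without a pair. The cause was not tested. Of the blocked calls, 89.2% were lower among the dimmest genes and 61.1% among the brightest, of 3 classes with equally many genes. Median Cy5 signal was only 2.14 to 3.66 times its background, a limit for the dim genes. Whether it plays a part in these shares was not tested. The block changed none of camera's calls over the 24 lists, but fry called 5 with it and 0 without. The mean correlation of same-numbered arrays was 0.892, and 0.888 with the scanner's ratios. Aquantile leaves ratios as they are, so it tested nothing. Slide and scan could not be run as a block, since there was 1 of each.

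For 9 lists the direction of camera's test turned in some setting, with no call there (adjusted p 0.101 or more); the cause was not tested. The adipocyte median was 0.063 with offset 16, -0.023 under median centring, 0.092 without a filter, 0.048 with array weights and 0.029 with the replicate block. The junction median was 0.17 with the scanner's ratios, 0.17 with the deposited table and 0.12 with array weights. The intestinal median was 0.067 without a filter, 0.067 among probes above background on all 6 arrays, 0.086 with array weights and 0.14 by fry. The transition median was 0.22 among probes above background on all 6 arrays, the cell cycle median 0.022 with array weights, and the erythroid and muscle median -0.19 under median centring, where Acta1 was at -0.22. Without an array or a pair, medians were -0.14 to 0.22 for junction, -0.20 to 0.17 for cell cycle, -0.13 to 0.067 for immediate early, -0.18 to 0.12 for leukocyte, -0.14 to 0.14 for adipocyte, 0.030 to 0.14 for intestinal, -0.040 to 0.35 for basement membrane, and 0.054 to 0.22 for erythroid and muscle genes.

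The real grouping gave 96 genes and the highest of the other splits 0, so 1 of 10 splits gave as many; of the splits that part all pairs, 1 of 4 gave as many with the block (1210, highest other 0). These splits are too few for a share under 0.05.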

Other observations

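The tests against the dimmer Cy5 channel, and the 5 added marker lists, were chosen after the tables of top genes had been seen; the lists were written before the values of their other members were looked at. Gcnt1 and Bst1, already seen lower, sit in the venule and reticular lists, and Cd34, Foxc2, Thy1 and Grem1 are also in fixed lists. High endothelial venules are the vessels through which lymphocytes enter lymph nodes. Their 10 tested genes had a median of -1.51, and 7 fell with the block, among them Gcnt1, St3gal6 (-3.04), Ackr1 (-2.11) and Sele (-1.73). Glycam1 had a ratio difference of only -0.91 (adjusted p = 0.037 with the block), although its normalized log2 Cy5 signal was 14.4 in Lgr5-positive and 18.5 in Lgr5-negative cells. Lymphatic endothelial genes had a median of -0.33 (9 genes; 4 fell with the block and Pdpn, at 0.61, rose), and lymph node reticular genes -0.60 (10 genes; 4 fell and Pdpn rose). With an estimated correlation the adjusted p of the 3 lists was 0.072, 0.107 and 0.093, and 0.229 to 0.239 with the block.

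Endothelial markers were lower in Lgr5-positive cells. The list's median of -2.04 lay outside the central 95% of brightness-matched random lists (-0.17 to 0.18), which ignore correlation between genes. Loess centres genes of any brightness on each array, and the median was known when the comparison was chosen. The comparison therefore cannot decide whether a dimmer Cy5 channel on the Lgr5-positive arrays played a part. Endothelial cells in the Lgr5-negative fraction may account for the pattern, since 24 pan-endothelial genes outside the fixed list had a median of -1.96 (matched lists -0.11 to 0.13) and 19 fell with the block, among them Mmrn2 (-2.66), Tspan7 (-2.17) and Cd34 (-2.58, with -0.46 on a second probe), with 2 past the test with the group alone and an adjusted p for the list of 0.072 with an estimated correlation (0.229 with the block). Aplnr (-0.26), Clec14a (-0.22), Gpihbp1 (-0.12), Myct1 (-0.10) and Arhgef15 (-0.04) did not pass, and 20 of the 24 genes were also well above background on all Lgr5-positive arrays. The Lin gate would remove such cells only if it held an endothelial marker, which the labels do not say, and vascular genes expressed by Lgr5-negative mammary cells themselves stay open as an untested alternative.

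Interferon-stimulated genes were also lower. Their median of -0.86 lay outside matched lists (-0.13 to 0.15), which for the same reasons cannot decide about the dimmer channel. With an estimated correlation camera's adjusted p for the list was 0.227 (0.496 with the block). Whether they came with endothelial cells could not be settled. If so, the medians of both lists had been predicted to rank alike over the pairs. In pairs 1 to 3 they were -2.26, -1.35 and -2.50 for the endothelial list and -0.53, -0.84 and -1.19 for the interferon list. They did not rank alike, as pair 1 had the smallest interferon fall and pair 2 the smallest endothelial fall. With 3 pairs, none of which lacked the endothelial difference, this cannot decide the question. A lower interferon response in Lgr5-positive cells remains a hypothesis.

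Motile cilium genes were looked at because Foxj1, the main regulator of motile cilia (1.33), Nme5 (1.35), Enkur (1.19), Rsph9 (1.04), Odf3b (0.96) and Ccdc153 (0.90) were seen among the genes that rose with the block; all 6 missed the threshold with the group alone (adjusted p 0.098 to 0.579). Of 40 other cilium genes listed, 23 were tested, and the rest have no value here. The median of these 23 was 0.17 (matched lists -0.10 to 0.10), so it lay above the matched lists also outside the genes first seen. Of them 17 lay above 0 and 6 below, and 3, Rsph1, Mlf1 and Tppp3, passed the test with the block. Others, such as Hydin (-0.0072) and Dnaaf1 (0.0095), lay near 0. Among the 23, the 17 genes well above background on all arrays also had a median of 0.17 (matched lists -0.09 to 0.14). The shift is small, and the matched lists ignore correlation between genes. With an estimated correlation camera's adjusted p was 0.072 (0.229 with the block). These comparisons therefore cannot decide whether picking from the top genes or signal near background played a part. A ciliated or Foxj1-positive trait of Lgr5-positive cells may be worth a direct test, as a hypothesis only.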
